A study of Rattus norvegicus with 36 samples.

How the data were processed

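Kidney RNA of 31 rats was measured on 36 CodeLink arrays with 9911 probes, 2 arrays for each of 5 rats, where per the labels separate RNA aliquots were processed. Labelling followed the CodeLink standard protocol with biotin, per the labels. The scanner software, the background correction and the scaling of the arrays are not given in the sources used here.

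The deposited unit is an unusual one, recorded as "other": each deposited value is 2 raised to the power of an intensity that had been divided by about its array's median. This was read from the values. The log2 of all 347608 tested values were whole multiples of 0.0001 within 1e-06, where chance gives 2.0%, the array medians of log2 lay between 0.999 and 1.0, and the highest log2 was 322.7. The log2 of a deposited value was therefore taken as the linear intensity, and the rule for linear intensities fixed in the design was applied to it, a reading made after seeing the values. A deposited 0.5 (log2 of -1.0) was a fill value and was treated as missing, 0.97% of all values.

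In sham rat 3 the values were out of line with the probe names by 2 lines. Its correlation with the median of the other arrays was 0.0652 as deposited and 0.9843 once moved by 2, against 0.9163 to 0.9889 in the other arrays. The moved values were used, a decision made after seeing the data, with the deposited order as an alternative.

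Intensities were divided by the array median, set to a floor of 0.1 of the median and brought to log2. The array medians of the deposited log2 values spanned 0.001, under the limit of 0.1 above which quantile normalization would have been used. Per array, 70 to 172 probes were missing, 1.65% to 12.91% of probes lay at the floor, and the 90th percentile was 2.744 to 3.16 on the log2 scale. The 2 arrays of a rat were averaged with limma's avearrays, so that each rat counted once. The SD of the log2 difference between the 2 arrays of a rat was 0.177 to 0.457, against a median of 0.263 to 0.592 between rats of the same group.

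The deposited description gives 2 array lots of 24 and 12 arrays with 3 normal in each, while the labels give 5 normal rats on 7 arrays, and no label ties an array to a lot. The number series of the normal rats were assumed to mark the lots. Following a rule fixed in the design, each array of the treated groups was scored by the correlation of its profile with the difference between normal rats 11 and 12 and normal rats 1 to 3. The widest gap between scores, from -0.017 to 0.298, parted 20 arrays from 9 and kept every group whole, giving lots of 24 and 12 arrays. With sham rat 3 as deposited the gap parted 21 from 8 arrays and a group was divided, in which case the rule left the lot out. On the arrays of lot 2, 47 probes were missing throughout and on none of lot 1, with 8 probes the other way round and 23 missing on all arrays. The median absolute log2 difference between the normal rats of the lots was 0.182.

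Probes were named from the array annotation, with 51 named through their RefSeq accession and the gene table of the rat assembly GRCr8 used for current symbols. Of all probes 7229 had 1 symbol, 21 several and 2661 none, giving 6444 symbols. A gene with several probes was represented by its brightest. A probe was tested where at least 2 rats of each group compared and 2/3 of all rats were measured and at least 3 rats lay above the floor.

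All groups were fitted together with limma 3.58.1 (lmFit and eBayes; R 4.3.3, statmod 1.5.0), with group and lot as terms and 21 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg over the probes of each comparison, and an adjusted p under 0.05 was called. There were 16 comparisons: 8 with the normal rats, and 8 between treated groups, of which those of groups in different lots are differences of each group's change from the normal rats of its lot. Intervals are at the 95% level. Replicate numbers did not pair the rats, so no replicate block was used.

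The 21 gene lists were immediate early genes, heat shock proteins, oxidative stress and metallothionein, tubular injury, proximal tubule, loop of Henle with distal tubule and collecting duct, leukocytes, cytokines with chemokines and adhesion molecules, p53 targets and apoptosis, unfolded protein and integrated stress response, hypoxia and glycolysis, fatty acid oxidation, renin-angiotensin and sodium handling, glucocorticoid responsive, circadian clock, cell cycle, endothelium, glomerulus, fibroblast and smooth muscle, red blood cell, and adrenal gland and fat tissue. Some genes are in several lists. Lists with at least 5 measured genes (20 of 21) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Gene counts per list are given at the threshold over all probes and adjusted over the list alone.

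The genes named were chosen by rule. In each comparison with normal rats these were up to 10 with the largest rise and up to 10 with the largest fall among those called, with 1 symbol (uncharacterised genes left out) and every rat on the same side of the mean of the normal rats of its lot. In the other comparisons up to 5 each way were taken, with no overlap between the rats of the groups where they shared a lot. The largest called members of a list, or its 2 largest changes where none was called, and Havcr1, Lcn2, Hmox1, Fos, Atf3 and Cdkn1a were added. Not every gene the rule allows is printed, and those whose calls held when each rat was left out were preferred, a preference made after seeing the data. A gene at the floor in all rats of a group is given as a lower bound.

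Alternatives fixed before the values were seen were no lot term, quantile normalization, a floor of 0.3, no floor, no filter on dim probes, only probes above the median brightness, a trended and robust prior, only the groups compared, the first array of each rat, the rat as a random block, a replicate block, an adjusted p under 0.01, a fold of at least 2, the median over a gene's probes, an estimated correlation, and leaving out each rat. Added after seeing the data were the deposited order of sham rat 3 with and without the lot term, array weights, leaving out the doubted arrays, leaving out normal rats in comparisons across lots, and no lot term for the lists. Other splits of the rats were fitted for each comparison, at most 100.

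The tests were tried on simulated data with 200 changed probes and 5 simulations per comparison. For ischemia 2 h against normal 83.6% of 2-fold changes were recovered, with 4.8% of calls false, and the median SE of a log2 change was 0.163. Across the lots, for mercuric chloride at 8 h against 2 h, that SE was 0.261. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.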

Results

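Gene expression was measured in kidneys of male rats on 36 CodeLink arrays, 1-colour oligonucleotide arrays with 9911 probes. The arrays came from 31 rats in 9 groups, and 5 rats had 2 arrays each. Untreated normal rats numbered 5. Ischemia rats had both kidneys deprived of blood for 40 min and were studied after 2 h (4 rats) or 8 h (3 rats) of reperfusion. A further 3 rats received 50 µg of alpha melanocyte stimulating hormone (αMSH), an anti-inflammatory peptide, with the ischemia and were studied at 2 h. The nephrotoxins were mercuric chloride at 4 mg/kg, studied at 2 h and 8 h (3 rats each), and cisplatin at 20 mg/kg, studied at 2 h (3 rats). Controls were 3 rats studied 8 h after 40 min of sham surgery and 4 rats made volume depleted, studied at 24 h. Volume depletion was by furosemide, a loop diuretic, at 20 mg/kg, with a second furosemide dose at 8 h, and a low-sodium diet. The number of arrays limited the precision.

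The arrays were parted into 2 lots of 24 and 12 from their values, on the assumption that the 2 number series of the normal rats marked the lots, since no label gives the lot of an array. This puts 3 normal rats in lot 1 and 2 in lot 2, where the deposited description counts 3 normal for each lot. Sham, cisplatin and 8 h mercuric chloride rats lay in lot 2 and all other treated groups in lot 1, so each effect was measured against the normal rats of its lot. Counts below are of probes past a Benjamini-Hochberg adjusted p of 0.05 in limma, changes are on the log2 scale with their SE, and gene lists were tested with camera. Groups, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. For the largest changes that rule required every rat on the same side of the normal mean, or no overlap between groups of a lot. Where this is said of such genes below, it follows from the rule and is no added evidence. In the 2 lot 2 normal rats the immediate early genes were lower than in the 3 lot 1 normal rats, with a list median of -0.59 and 12 of 15 genes lower. The glucocorticoid responsive genes were also lower there, with a median of -0.36. Cell cycle genes were higher there, with a median of 0.22 and 1 of 12 genes lower, though 95% of random lists matched on mean expression lay between -0.14 and 0.25. Leukocyte genes had a median of -0.17 there, with 13 of 18 lower, and endothelium genes 0.17, with 4 of 10 lower. Among random lists these 2 medians were at percentiles 2.37 and 98.08. Proximal tubule genes had a median of -0.21 there, with 20 of 28 lower, at percentile 3.75. Oxidative stress and metallothionein genes had a median of -0.24, with 13 of 16 lower, at percentile 6.07. Of the clock genes, Dbp was higher and Bmal1 lower in the lot 2 normal rats. Whether the rats or the array lots differed in these genes is not known. Nor is it known which lot's normal rats were unusual, so this bears on the clock genes in the lot 1 groups as well. These facts bear on every value for members of these lists in sham, cisplatin and 8 h mercuric chloride rats, and a value with no lot term is given below where the called change of a gene named for these rats moved by over 1.5 times. The array of ischemia 8 h rat 3 stood apart from its group, with a median correlation of 0.926 with it and 1.65% of probes at the floor. That array, the array of normal rat 1 and the first array of volume depletion rat 1 are called the doubted arrays below, a choice made after seeing the data.

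**Figure D1:**
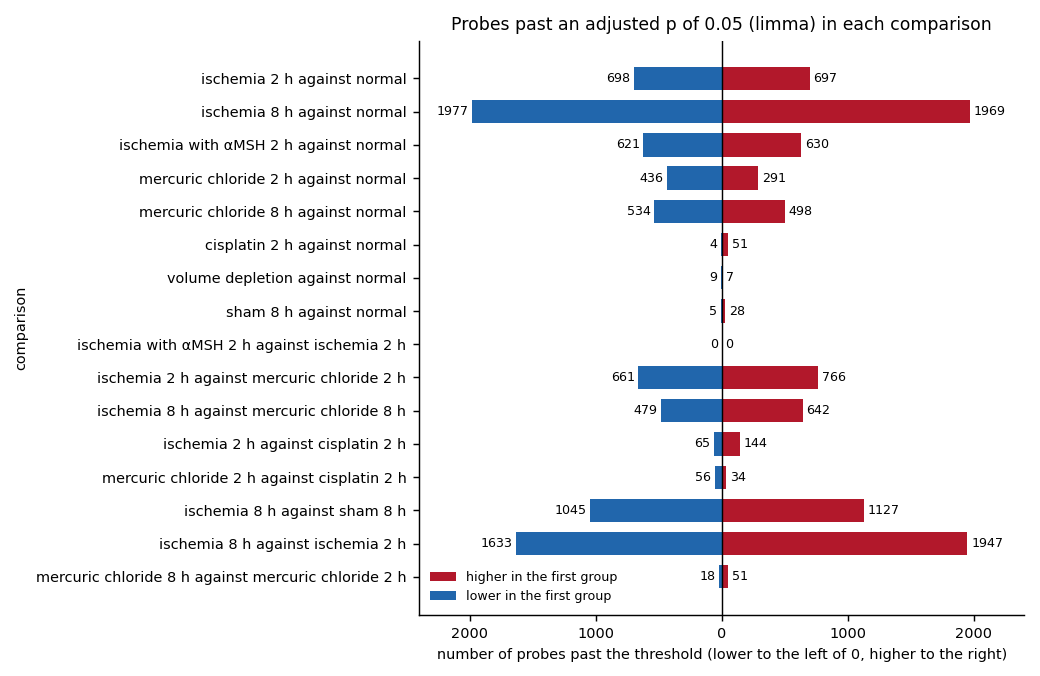
Number of probes past an adjusted p of 0.05 (limma) in each of the 16 comparisons, with probes higher in the first group drawn to the right of 0 and lower ones to the left. The counts run from 0 (ischemia with αMSH against ischemia at 2 h) to 3946 (ischemia 8 h against normal).

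The response to ischemia and its surgery within 2 h of reperfusion was asked first, with 4 ischemia and 3 normal rats. No sham rats were studied at 2 h, so changes from surgery and from ischemia cannot be told apart at that time. Fos, an immediate early transcription factor, rose by 6.16 ± 0.66 (71.4-fold), and the inducible heat shock protein Hspa1a rose by 5.96 ± 0.32 (62.4-fold). The zinc finger factors Egr1 (27.8-fold) and Klf6 (19.1-fold) and the stress factor Atf3 (17.9-fold) rose as well. Chac1, a glutathione-degrading enzyme of the integrated stress response, rose by 4.08 ± 0.18 (17.0-fold) and the chemokine Ccl20 by 3.95 ± 0.42 (15.5-fold). The muscle LIM protein Csrp3, at the floor in normal rats, was at least 12.5-fold higher. Falls were smaller: Purg fell by 1.54 ± 0.12, the immune cell gene Ly86 by 1.36 ± 0.25 and Gp2 by 1.33 ± 0.23. Each gene so far lay on the same side of the mean of the normal rats in all 4 ischemia rats. Lcn2, a secreted marker of tubular injury, rose 2.88-fold, while the injury marker Havcr1 was at 0.31 ± 0.39 (adjusted p = 0.711).

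By gene list, 13 of 15 immediate early genes rose at 2 h of ischemia and none fell, the same counts when adjusted over the list alone. Of 21 cytokines, chemokines and adhesion molecules 12 rose and 0 fell (12 and 1 adjusted over the list alone), among them Cxcl1 (9.51-fold) and Il6 (6.46-fold). Of 15 tubular injury genes 9 rose (11 adjusted over the list alone), led by the urokinase receptor Plaur (3.27 ± 0.20). Of 13 unfolded protein and integrated stress response genes 6 rose (7 adjusted over the list alone), including the chaperone Hspa5 (2.89-fold) and the phosphatase subunit Ppp1r15a (6.84-fold). Heat shock proteins rose in 5 of 8 cases (6 adjusted over the list alone), with the small heat shock protein Cryab at 3.17-fold. Of 14 p53 targets and apoptosis genes 5 rose and 1 fell, with the cell cycle inhibitor Cdkn1a at 6.62-fold and the kinase Plk2 at 7.65-fold. The oxidative stress and metallothionein list had 2 of 17 members up, heme oxygenase Hmox1 (10.7-fold) and the peroxiredoxin reductase Srxn1 (12.7-fold), and its median (-0.08) and mean (0.35) differed in sign. Of 18 leukocyte genes 2 rose, S100a9 (11.5-fold) and Cd14, and 3 fell, among them Ptprc and Csf1r (2 and 5 adjusted over the list alone). Of 16 renin-angiotensin and sodium handling genes 1 rose, endothelin Edn1 (5.09-fold), and 1 fell, the mineralocorticoid receptor Nr3c2 (-0.79 ± 0.17).

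In all, 1395 of 9489 probes passed at 2 h of ischemia, 697 up and 698 down, of which 275 and 37 changed at least 2-fold. Without normal rat 1 there were 658 up and 352 down. Camera called 11 of 20 lists, and 8 of the calls also held with an estimated correlation: immediate early genes, heat shock proteins, tubular injury, cytokines, p53 targets, unfolded protein response, glucocorticoid responsive and circadian clock genes, all higher. The other calls had an adjusted p of 0.0596 (hypoxia and glycolysis, higher), 0.164 (fibroblast and smooth muscle, higher) and 0.2 (proximal tubule, lower) with an estimated correlation.

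αMSH is known to lessen ischemic injury, and the next question was whether it altered the response at 2 h. In the 3 rats given αMSH the largest rises over the 3 normal rats were again in Fos (6.04 ± 0.70, 66.0-fold) and Hspa1a (5.86 ± 0.35, 58.2-fold). Cxcl1, a neutrophil chemokine, rose 13.7-fold, Il6 11.4-fold and the adhesion molecule P-selectin, Selp, 9.65-fold. Of 9456 probes 1251 passed, 630 up and 621 down. Without αMSH rat 1 784 were left (494 and 290), without normal rat 1 791 (556 and 235) and without αMSH rat 3 955 (548 and 407). Immediate early genes rose in 13 of 15 cases, cytokines in 14 of 21 and tubular injury genes in 10 of 15 (13, 14 and 11 adjusted over the list alone). Camera called 11 lists against normal, and 7 held with an estimated correlation: immediate early genes, heat shock proteins, tubular injury, cytokines, unfolded protein response, glucocorticoid responsive and circadian clock genes. The p53 list (adjusted p = 0.16), hypoxia and glycolysis (0.148), proximal tubule (0.337) and the loop of Henle, distal tubule and collecting duct (0.254) were called with the preset correlation alone, each p with an estimated correlation.

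In the direct comparison of 3 ischemia rats with αMSH and 4 without, no probe passed in limma. At an unadjusted p under 0.05 there were 342 of 9456 probes, and the smallest adjusted p was 0.704. The 95% interval of the difference ran from -1.48 to 1.26 for Fos, from -0.25 to 0.89 for Hmox1, from -0.31 to 0.59 for Lcn2 and from -0.88 to 0.72 for Havcr1. Camera with the preset correlation placed cytokines, chemokines and adhesion molecules higher with αMSH (adjusted p = 6.63e-05, median 0.16), with an adjusted p of 0.165 with an estimated correlation. Of its 21 members 0 passed (3 higher adjusted over the list alone), and the largest differences were in Ccl4 (1.29 ± 0.52) and Selp (1.18 ± 0.37). The cell cycle list (median -0.33, adjusted p = 0.165 with an estimated correlation), the p53 list (median -0.17, 0.165) and the loop of Henle list (median -0.19, 0.58) were lower, none with a member past the threshold. Without αMSH rat 3 the count was 2 probes, and without ischemia 2 h rat 3 it was 1. On simulated data of this design, with 200 probes changed at once and the same spread in every rat, 86% of 2-fold and 45.1% of 1.5-fold changes were recovered. With few changed probes the adjusted threshold is stricter. These shares therefore do not give the power to find a few changes here.

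The state of the kidney 8 h after ischemia was measured in 3 rats against the 3 normal rats of the lot. Hspa1a (5.86 ± 0.35, 58.2-fold) and Hmox1 (5.13 ± 0.29, 35.1-fold) rose most, followed by the neutrophil protein S100a9 (32.4-fold). The injury markers Havcr1 (4.94 ± 0.41, 30.7-fold) and Lcn2 (4.72 ± 0.23, 26.3-fold) rose, as did the cell adhesion receptor Pvr (28.1-fold) and Plaur (21.6-fold). The cytokine Il24, at the floor in normal rats, was at least 26.1-fold higher. Among the falls were the phosphatase inhibitor Ppp1r1a (fold 8.72), the glucagon receptor Gcgr (-2.53 ± 0.14), the sodium-proton exchanger Slc9a3 (-2.39 ± 0.34) and Egf (-2.33 ± 0.19), a growth factor of the distal nephron. All of these lay on the same side of the normal mean in each of the 3 rats.

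Markers of differentiated tubules fell in this comparison. Of 28 proximal tubule genes 21 fell and none rose (25 adjusted over the list alone), with G6pc1, the last enzyme of gluconeogenesis, at -2.11 ± 0.27 and the creatine synthesis enzyme Gatm at -1.57 ± 0.18. Of 14 genes of the loop of Henle, distal tubule and collecting duct 8 fell and 2 rose, including the loop transporter Slc12a1 (-1.91 ± 0.23), with an adjusted p of 0.254 for the list with an estimated correlation. Fatty acid oxidation genes fell in 14 of 23 cases and rose in 2 (15 and 2 adjusted over the list alone), with the peroxisomal enzyme Ehhadh at -2.20 ± 0.23 and an adjusted p of 0.254 with an estimated correlation. Tubular injury genes rose in 13 of 15 cases, the chaperone clusterin, Clu, by 3.12 ± 0.33. Of 14 p53 targets and apoptosis genes 11 rose and 1, Sesn1, fell (-1.74 ± 0.12). Unfolded protein and integrated stress response genes rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone). Of 18 leukocyte genes 7 rose and 0 fell, among them Cd14 (3.99-fold) and the complement gene C1qb (3.56-fold), with an adjusted p of 0.0926 for the list. Of 18 hypoxia and glycolysis genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with the glycolytic enzymes Pkm (3.59-fold) and Ldha (2.71-fold) up and an adjusted p of 0.254 with an estimated correlation.

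At 8 h of ischemia 3946 of 9489 probes passed, 1969 up and 1977 down, and 4294 passed without the doubted arrays (1949 and 2345). Without ischemia 8 h rat 3 there were 1835 up and 2511 down, and without ischemia 8 h rat 1 2192 and 1766. The camera calls that held with an estimated correlation were tubular injury, p53 targets and the unfolded protein response, higher, and the proximal tubule, lower, each at 0.0464. The remaining 6 called lists had adjusted p values of 0.062 (heat shock proteins), 0.102 (cytokines) and 0.254 (the others, immediate early genes among them) with an estimated correlation.

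**Figure D2:**
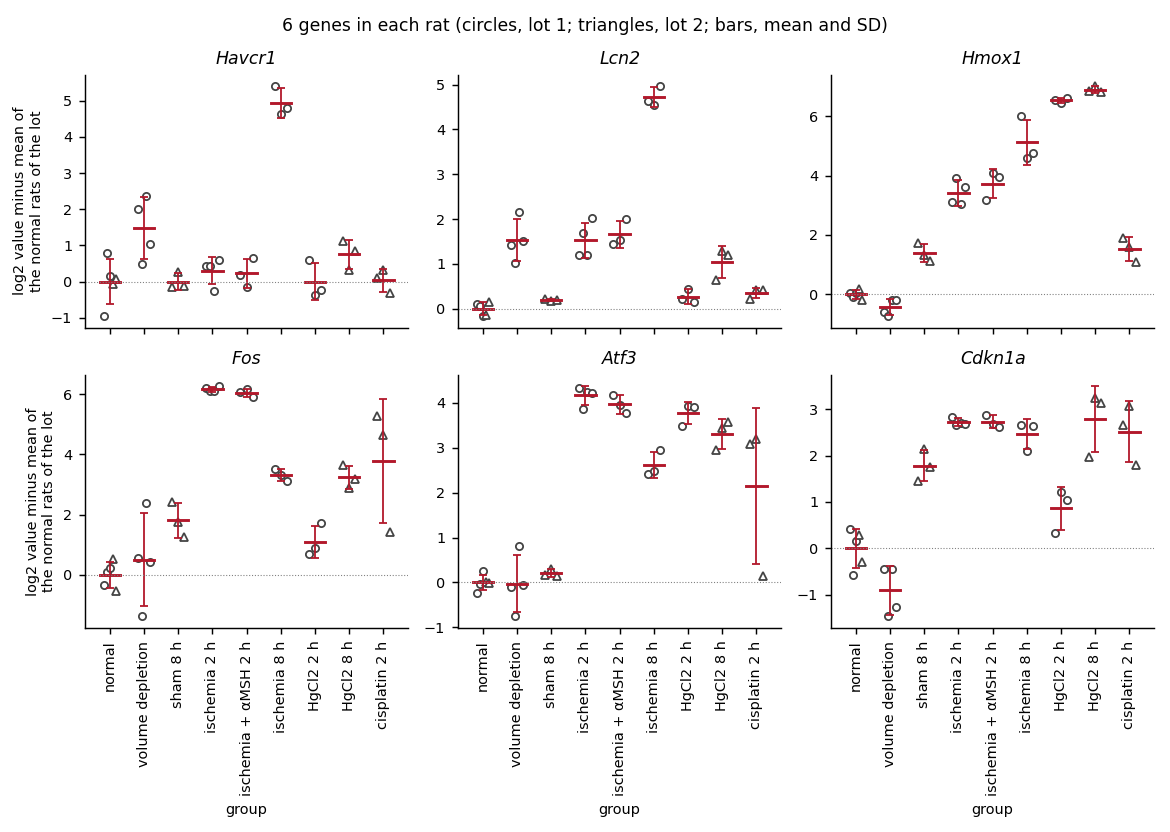
Log2 value of Havcr1, Lcn2, Hmox1, Fos, Atf3 and Cdkn1a in each of the 31 rats minus the mean of the normal rats of its lot, by group, with the group mean and SD. Havcr1 stood highest in the 3 ischemia 8 h rats (mean change 4.94), and Hmox1 was highest in the mercuric chloride rats (6.54 at 2 h and 6.90 at 8 h).

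How mercuric chloride acted within 2 h was asked with 3 treated and 3 normal rats. Hmox1, which degrades heme and responds to oxidants and metals, rose by 6.54 ± 0.29 (93.1-fold). Chac1 rose by 5.92 ± 0.19 (60.3-fold) and Hspa1a by 5.04 ± 0.35 (32.9-fold), followed by Srxn1 (14.2-fold) and Atf3 (13.7-fold). The growth factor Areg rose 8.55-fold and the mitochondrial folate enzyme Mthfd2 6.92-fold. Among the falls were the carrier Slc16a6 (-1.91 ± 0.22), the carbonic anhydrase Car14 (-1.91 ± 0.20) and the collagen-modifying protein Crtap (-1.65 ± 0.20). Each of these genes lay on the same side of the normal mean in all 3 rats. Havcr1 (0.00 ± 0.41), Lcn2 (0.27 ± 0.23), Fos (1.10 ± 0.70) and Cdkn1a (0.86 ± 0.35) did not pass, with adjusted p values of 1.0, 0.556, 0.389 and 0.144.

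Unfolded protein and integrated stress response genes rose in 5 of 13 cases and none fell (6 and 1 adjusted over the list alone) at 2 h of mercuric chloride. Heat shock proteins rose in 2 of 8 cases (3 adjusted over the list alone). These lists were the 2 of 9 called by camera whose calls held with an estimated correlation (adjusted p = 0.00944 and 0.0397). Of 15 immediate early genes 5 rose (7 adjusted over the list alone) and of 17 oxidative stress genes 3 rose (5 adjusted over the list alone), each list with an adjusted p of 0.17 with an estimated correlation. Proximal tubule genes fell in 6 of 28 cases (9 down and 1 up adjusted over the list alone), including Gatm (-1.30 ± 0.18) and the amino acid transporter Slc7a9 (-1.17 ± 0.15), with an adjusted p of 0.17 with an estimated correlation. Of 21 cytokines, chemokines and adhesion molecules 2 rose, with a list median of -0.02, a mean of 0.22 and an adjusted p of 0.056. Of 9465 probes 727 passed, 291 up and 436 down. That count was 474 without normal rat 1 (280 up and 194 down), 480 without normal rat 2 (183 and 297), 370 without mercuric chloride rat 1 (174 and 196) and 418 without mercuric chloride rat 3 (198 and 220). Without the doubted arrays 528 rose and 519 fell, and among changes of at least 2-fold 77 rose and 55 fell, so the excess of falls depended on the rats and the threshold.

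At 8 h of mercuric chloride, in 3 rats against the 2 normal rats of lot 2, Hmox1 stood at 6.90 ± 0.33 (120.0-fold) and Hspa1a at 6.15 ± 0.39 (71.2-fold). The glucuronosyltransferase Ugt2b7 rose by 5.80 ± 0.71 (55.7-fold), Chac1 39.6-fold, Srxn1 29.2-fold and the cytokine receptor Tnfrsf12a 11.4-fold. G6pc1 fell by 2.94 ± 0.30 (fold 7.66), the carnitine carrier Slc22a5 by 1.75 ± 0.23 and Fn3k, a kinase of glycated proteins, by 1.87 ± 0.16. All of these changes had the same sign in each of the 3 rats. Lcn2 rose 2.05-fold (adjusted p = 0.00865), a call that ended without normal rat 11 (0.89 on the log2 scale), and Havcr1 was at 0.76 ± 0.46 (adjusted p = 0.369).

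Oxidative stress and metallothionein genes rose in 8 of 17 cases (10 adjusted over the list alone), with the quinone reductase Nqo1 at 5.36-fold and an adjusted p of 0.054 with an estimated correlation. Heat shock proteins rose in 4 of 8 cases (8 adjusted over the list alone, adjusted p = 0.00352 with an estimated correlation). Of 13 unfolded protein and integrated stress response genes 4 rose (6 adjusted over the list alone, adjusted p = 0.0106 with an estimated correlation). Proximal tubule genes fell in 10 of 28 cases and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0497 with an estimated correlation). These 3 calls alone, of 11, held with an estimated correlation. Of 15 immediate early genes 10 rose (12 adjusted over the list alone, adjusted p = 0.0596 with an estimated correlation). Cell cycle genes fell in 3 of 12 cases (4 down and 1 up adjusted over the list alone), among them Cdk1 (-1.34 ± 0.28) and Ccna2 (-1.29 ± 0.28), or -1.26 and -0.97 with no lot term, with an adjusted p of 0.0803 for the list. Of 14 genes of the loop of Henle, distal tubule and collecting duct 0 passed, with a median of 0.03. In all, 1032 of 9489 probes passed, 498 up and 534 down, against 1993 without the doubted arrays, 505 without normal rat 11 (281 up and 224 down) and 472 without normal rat 12 (250 and 222). With no lot term the count was 2145.

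Cisplatin, a DNA-damaging drug, was compared at 2 h in 3 rats with the 2 normal rats of lot 2. The changes were fewer, and 51 of the 55 passing probes rose. Zfp36, which destabilises cytokine messages, rose by 2.44 ± 0.36 (5.42-fold), Hspa1a by 2.44 ± 0.39 (5.41-fold) and the glucocorticoid-inducible factor Cebpd by 1.96 ± 0.32. With no lot term Zfp36 stood at 1.58 and Cebpd at 1.21. The p53 targets Gadd45a (1.72 ± 0.27, 1.13 with no lot term) and Cdkn1a (2.52 ± 0.39) rose, Cdkn1a losing its call without normal rat 12 (2.23). Cdkn1a was also called in sham rats, and its mean was lower in the normal rats of lot 2 (-0.31) than in those of lot 1 (0.90). Fos stood at 3.79 ± 0.79 (13.8-fold, adjusted p = 0.0223), with an SD of 2.06 between the 3 rats, and its call ended without normal rat 11 (4.31), normal rat 12 (3.27), cisplatin rat 2 (3.04) or cisplatin rat 3 (3.36). Havcr1 (0.04 ± 0.46) and Lcn2 (0.35 ± 0.26) did not pass, both at an adjusted p of 1.0.

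Of 15 immediate early genes 6 rose in cisplatin rats (12 adjusted over the list alone, median 2.15). Cisplatin rat 1 stood apart, with Fos at 1.44 over the normal mean against 5.29 and 4.65 in the other 2 rats and Atf3 at 0.14 against 3.09 and 3.20. Of 14 p53 targets and apoptosis genes 2 rose and 1 fell (5 and 1 adjusted over the list alone) and of 10 glucocorticoid responsive genes 3 rose (4 up and 1 down adjusted over the list alone). These 3 lists were the 3 of 6 camera calls that held with an estimated correlation, at adjusted p values of 0.0033, 0.0196 and 0.00061. None of 28 proximal tubule genes passed (median -0.09). The call count was 15 without cisplatin rat 2, 29 without rat 3 and 142 without rat 1, and 18 without normal rat 12, while 509 probes passed with no lot term and 112 without the doubted arrays. With quantile normalization 50 rose and 13 fell.

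Volume depletion served as a control for acute renal failure, and 4 rats were compared with 3 normal rats to ask which genes it changed. Dbp, a transcription factor of the circadian clock output, rose by 2.11 ± 0.20 (4.31-fold), and Bmal1, the core activator of the clock, fell by 2.33 ± 0.30 (fold 5.03). Lcn2 rose by 1.53 ± 0.22 (2.89-fold) and the matrix protein Tnc fell by 1.17 ± 0.18. All 4 rats showed each of these directions. Gatm fell by 0.97 ± 0.17, a call that ended without normal rat 1 (-0.85), and the phosphatase Dusp7 fell by 1.25 ± 0.20, a call that ended with no lot term (-0.86). Havcr1 stood at 1.48 ± 0.39 with an adjusted p of 0.188.

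Of 9464 probes 16 passed in volume depletion, 7 up and 9 down, and 48 passed without the doubted arrays. The count was 7 without normal rat 1, 10 without normal rat 3 and 8 without volume depletion rat 3. Of 9 circadian clock genes 1 rose and 1 fell (4 and 1 adjusted over the list alone), with an adjusted p of 0.199 for the list with an estimated correlation. Tubular injury genes rose in 1 of 15 cases (4 adjusted over the list alone, adjusted p = 0.0898 with an estimated correlation). Of the 16 renin-angiotensin and sodium handling genes 0 passed. None of the 6 camera calls held with an estimated correlation.

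**Figure D3:**
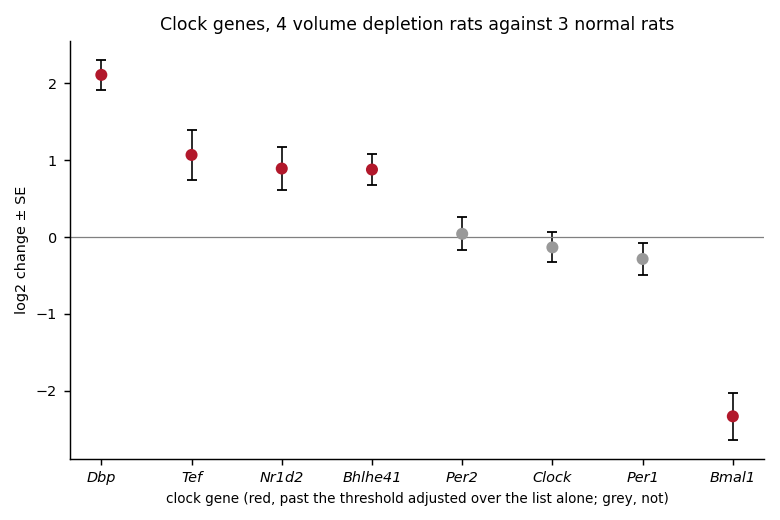
Log2 change (± SE) of 8 circadian clock genes in 4 volume depletion rats against the 3 normal rats of the lot, with genes past the threshold adjusted over the list alone in red. Dbp (2.11), Tef (1.07), Nr1d2 (0.89) and Bhlhe41 (0.88) were higher and Bmal1 (-2.33) was lower.

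Sham surgery, the control for ischemia, was compared at 8 h in 3 rats with the 2 normal rats of lot 2. Slc25a25, a mitochondrial carrier, rose by 2.98 ± 0.29 (7.89-fold) and Cebpd by 2.25 ± 0.32 (4.74-fold), the former at 1.68 with no lot term. The clock gene Per1 rose by 1.61 ± 0.25, a call that ended with no lot term (0.82), and the matricellular gene Ccn2 by 1.71 ± 0.31, a call that ended with no lot term (0.58), without sham rat 1 (1.46), without normal rat 11 (1.68) or without normal rat 12 (1.74). Cdkn1a rose by 1.79 ± 0.39 (adjusted p = 0.0428), a call that ended with no lot term (1.06) and without any of the 3 sham rats, normal rat 2, normal rat 11 or normal rat 12 (1.49 to 2.08). Havcr1 (-0.00 ± 0.46), Lcn2 (0.19 ± 0.26) and Hmox1 (1.40 ± 0.33) did not pass, with adjusted p values of 1.0, 1.0 and 0.0634. Glucocorticoid responsive genes rose in 3 of 10 cases (5 up and 1 down adjusted over the list alone, median 0.75), and circadian clock genes in 2 of 9. These lists, at adjusted p values of 1.9e-05 and 0.0221, held with an estimated correlation, and the other 8 camera calls did not.

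In sham rats 33 of 9489 probes passed, 28 up and 5 down, with 249 when no lot term was used and 61 without the doubted arrays. The count was 9 without sham rat 1, 17 without rat 2 and 13 without rat 3, and 11 without normal rat 12.

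Whether ischemia at 8 h differed from its own surgical control was asked across the lots. In this and the other comparisons across lots, the value is the difference between each group's change from the normal rats of its lot, so the means of the 2 groups do not subtract to it. Against 3 sham rats, 3 ischemia rats had higher Havcr1 (4.94 ± 0.62, 30.7-fold), Hspa1a (4.87 ± 0.52, 29.3-fold), Lcn2 (4.53 ± 0.35, 23.0-fold), Plaur (16.6-fold) and Hmox1 (13.3-fold). The calcium-sensing receptor Casr (-2.90 ± 0.48), Slc9a3 (-2.51 ± 0.50), Egf (-2.42 ± 0.28), Ehhadh (-2.35 ± 0.35) and G6pc1 (-2.24 ± 0.40) were lower. Of 28 proximal tubule genes 15 were lower and 0 higher (19 lower adjusted over the list alone), and of 10 glucocorticoid responsive genes 5 were lower, Per1 (-2.19 ± 0.34) and Klf9 (-1.72 ± 0.34) among them, at -0.85 and -1.02 with no lot term. Both calls held with an estimated correlation at an adjusted p of 0.025, unlike the other 9 camera calls. Tubular injury genes were higher in 10 of 15 cases and lower in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0816 with an estimated correlation). In all, 2172 of 9489 probes passed, 1127 higher and 1045 lower, but 1249 higher and 1654 lower without ischemia 8 h rat 3 and 1402 and 1579 without the doubted arrays. Without the lot term 4191 passed.

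The title comparison set ischemic against nephrotoxic injury, first at 2 h with 4 ischemia and 3 mercuric chloride rats of one lot. Surgery was part of the ischemia treatment alone, with no sham rats at 2 h to separate it. Fos was higher in ischemia by 5.05 ± 0.66 (33.2-fold) and the epithelial factor Klf4 by 3.48 ± 0.19 (11.2-fold). Ccn2 (8.46-fold), Plaur (8.28-fold), Il6 (7.53-fold), Edn1 (6.29-fold) and Trib1 (6.29-fold) were also higher in ischemia. Hmox1 was higher in mercuric chloride rats, by 8.73-fold (-3.13 ± 0.28), as were Ugt2b7 (8.11-fold) and Chac1 (3.55-fold). The rats of both groups did not overlap in Fos, Klf4, Hmox1, Ugt2b7 or Chac1. Atf3 differed by 0.39 ± 0.45 (adjusted p = 0.668). Immediate early genes were higher in ischemia in 11 of 15 cases, cytokines in 10 of 21 with 1 lower, and p53 targets in 7 of 14 (12, 10 and 7 adjusted over the list alone, the last with 1 lower). Each of these 3 lists had an adjusted p of 0.086 with an estimated correlation, and none of the 8 camera calls held with it. Endothelium genes were higher in 1 and lower in 3 of 11 cases (1 and 4 adjusted over the list alone), with the angiopoietin receptor Tek at -0.98 ± 0.24. Of 9465 probes 1427 passed, 766 higher in ischemia and 661 lower, and 2539 passed without the doubted arrays.

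At 8 h, across the lots, 3 ischemia rats had higher Havcr1 (4.18 ± 0.62, 18.1-fold), the tight junction gene Cgn (16.7-fold), Lcn2 (3.68 ± 0.35, 12.8-fold) and Plaur (10.8-fold) than 3 mercuric chloride rats. Ppp1r1a (-3.31 ± 0.26), Casr (-3.12 ± 0.48), Egf (-2.15 ± 0.28) and Chac1 (-2.16 ± 0.29) were lower in ischemia. Hmox1 was lower by 1.77 on the log2 scale (-1.77 ± 0.44), a call that ended without normal rat 12 (-1.58), and Fos differed by 0.08 ± 1.05 (adjusted p = 0.976), or 1.88 with no lot term (0.0589). Of 14 genes of the loop of Henle, distal tubule and collecting duct 5 were lower in ischemia and 1 was higher, Slc12a1 by -1.97 ± 0.34 (-1.23 with no lot term), with an adjusted p of 0.328 with an estimated correlation. Tubular injury genes were higher in 9 of 15 cases and lower in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.221 with an estimated correlation), and oxidative stress genes were lower in 5 of 17 cases, with the glutathione synthesis subunit Gclm at -1.32 ± 0.20 (adjusted p = 0.436 for the list with an estimated correlation). None of the 10 camera calls held with it. The count was 1121 of 9489 probes, 642 higher in ischemia and 479 lower, against 734 without normal rat 11 and 605 without normal rat 12, and 3122 with no lot term. Without ischemia 8 h rat 3 the larger part turned, with 721 higher and 890 lower.

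The overlap of both injuries was counted directly. At 2 h 139 probes rose in both ischemia and mercuric chloride rats, where independent lists would share 21.4, and 105 fell in both against 32.2. At 8 h 378 rose in both against 103.3, and 432 fell in both against 111.3. Fisher's exact test (one-sided, over probes, which are not independent) gave 4.19e-82 and 3.05e-29 at 2 h and 2.07e-164 and 2.21e-209 at 8 h. Hmox1, Hspa1a, Chac1, Srxn1 and Atf3 were among the genes that rose in both at both times. Of the probes that rose with mercuric chloride at 8 h, 75.9% also rose with ischemia, and of those that fell 80.9% also fell. Both 2 h groups were compared with the same 3 normal rats, which adds to the overlap by an amount that was not measured. The covariance of the log2 changes at 2 h was 0.0956, against 0.0266 in simulated groups without any effect, and the normal rats were too few to split between the groups. Without normal rat 1 the number falling in both at 2 h was 28, and it was 60 and 63 without mercuric chloride 2 h rats 1 and 3. At 8 h the numbers rising and falling in both were 214 and 193 without normal rat 11, and 191 and 199 without normal rat 12.

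**Figure D4:**
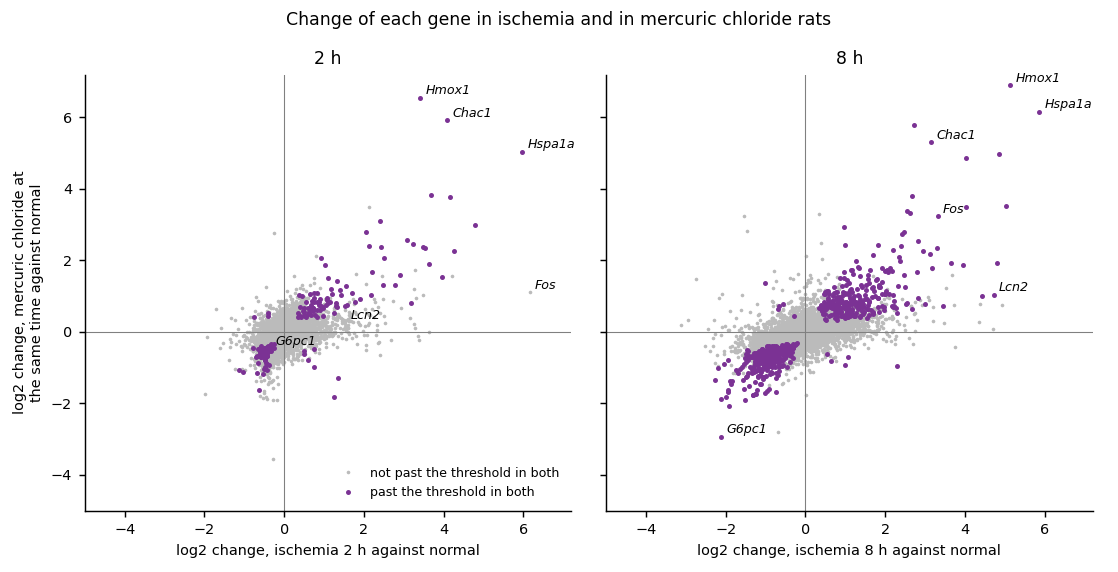
Log2 change of each gene in ischemia (horizontal axis) and mercuric chloride rats (vertical axis) against the normal rats of their lots, at 2 h and at 8 h, with genes past an adjusted p of 0.05 in both in purple. Over all probes, which are not independent replicates, Pearson's r was 0.516 at 2 h and 0.583 at 8 h.

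Ischemia and cisplatin were compared at 2 h, across the lots, with 4 and 3 rats. Chac1 (3.85 ± 0.28, 14.4-fold), Ccl20 (3.60 ± 0.65, 12.1-fold), Hspa1a (3.53 ± 0.51, 11.5-fold), the inositol kinase Itpkc (9.16-fold), Plaur (6.44-fold) and Klf4 (5.58-fold) were higher in ischemia. Fos differed by 2.37 ± 1.02 (adjusted p = 0.369), and was called with no lot term (4.17). Heat shock proteins were higher in 3 of 8 cases, unfolded protein and integrated stress response genes in 3 of 13 and cytokines in 4 of 21 (4, 5 and 11 adjusted over the list alone). These 3 calls of 8 held with an estimated correlation, at adjusted p values of 0.00285, 0.00285 and 0.0155. Of 9486 probes 209 passed, 144 higher in ischemia and 65 lower, against 121 without normal rat 11, 102 without normal rat 12, 2418 with no lot term and 365 without the doubted arrays.

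The 2 nephrotoxins were compared at 2 h, across the lots, with 3 rats each. Chac1 (5.68 ± 0.29, 51.3-fold), Hmox1 (5.02 ± 0.44, 32.4-fold), Srxn1 (6.68-fold) and Mthfd2 (5.19-fold) were higher with mercuric chloride. Trib1 (-1.98 ± 0.29), Cebpd (-2.29 ± 0.43) and Per1 (-2.36 ± 0.34) were lower, the last 2 at -1.04 and -1.03 with no lot term, as was Ccn2 (-3.04 ± 0.41), whose call ended with no lot term (-1.15). Glucocorticoid responsive genes were lower with mercuric chloride in 3 of 10 cases (4 adjusted over the list alone, adjusted p = 0.0206 with an estimated correlation), the 1 call of 7 that held. Of 9462 probes 90 passed, 34 higher and 56 lower, and with quantile normalization 88 were higher and 75 lower (140 and 118 without the doubted arrays). The count was 53 without mercuric chloride 2 h rat 3, 57 without cisplatin rat 2, 154 without cisplatin rat 1 and 33 without normal rat 12, and 2215 with no lot term.

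The time course of ischemia was read from 3 rats at 8 h and 4 at 2 h, in one lot. Havcr1 was higher at 8 h by 4.63 ± 0.39 (24.8-fold), the DNA repair gene Rdm1 by 3.99 ± 0.20 (15.9-fold), Lcn2 by 3.19 ± 0.22 (9.13-fold) and Il24 by 3.11 ± 0.20 (8.65-fold). Fos was lower by 2.85 on the log2 scale (-2.85 ± 0.66), Ppp1r1a by 6.57-fold and Gcgr by 4.76-fold. The rats of both times did not overlap in these 7 genes. Of 15 immediate early genes 9 were lower at 8 h and 1 was higher (10 and 1 adjusted over the list alone, adjusted p = 0.549 with an estimated correlation). Proximal tubule genes were lower in 15 of 28 cases (adjusted p = 0.0988 with an estimated correlation) and fatty acid oxidation genes in 15 of 23 (16 lower and 1 higher adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). Leukocyte genes were higher in 11 of 18 cases and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation), with the Fc receptor Fcgr3a at 1.59 ± 0.31 and C1qb at 1.33 ± 0.23. Glomerulus genes were higher in 3 and lower in 1 of 7 cases, Pdgfrb at 0.60 ± 0.12 and Clic5 at -0.59 ± 0.14. In all, 3580 of 9489 probes passed, 1947 higher at 8 h and 1633 lower, but 1651 higher and 1969 lower without ischemia 8 h rat 3 and 1830 and 2140 without the doubted arrays, and none of the 8 camera calls held with an estimated correlation.

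For mercuric chloride, 3 rats at 8 h were compared with 3 at 2 h across the lots. G6pc1 (-2.46 ± 0.40, fold 5.52), the mitotic gene Hmmr (-1.73 ± 0.26, -0.94 with no lot term) and Abhd17c (-1.48 ± 0.18) were lower at 8 h, and the neurofilament gene Nefm (2.94 ± 0.48) and Cebpd (2.31 ± 0.43, 1.07 with no lot term) were higher. Ccn2 (2.47 ± 0.42) and Per1 (1.77 ± 0.34) were higher too, calls that ended with no lot term (0.58 and 0.44), and that of Per1 ended without normal rat 11 (1.65). Hmox1 differed by 0.36 ± 0.44 (adjusted p = 0.934). Heat shock proteins were higher in 1 of 8 cases (2 adjusted over the list alone) and cell cycle genes lower in 1 of 12 (3 adjusted over the list alone), at adjusted p values of 0.207 and 0.352 with an estimated correlation. Of 9465 probes 69 passed, 51 higher and 18 lower, and with quantile normalization 100 were higher and 58 lower. Without the doubted arrays 103 were higher and 114 lower, with array weights 532 and 593, without normal rat 1 34 and 33, and without mercuric chloride 8 h rat 3 66 and 32. The count was 30 without normal rat 12 (18 and 12) and 1633 with no lot term.

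**Figure D5:**
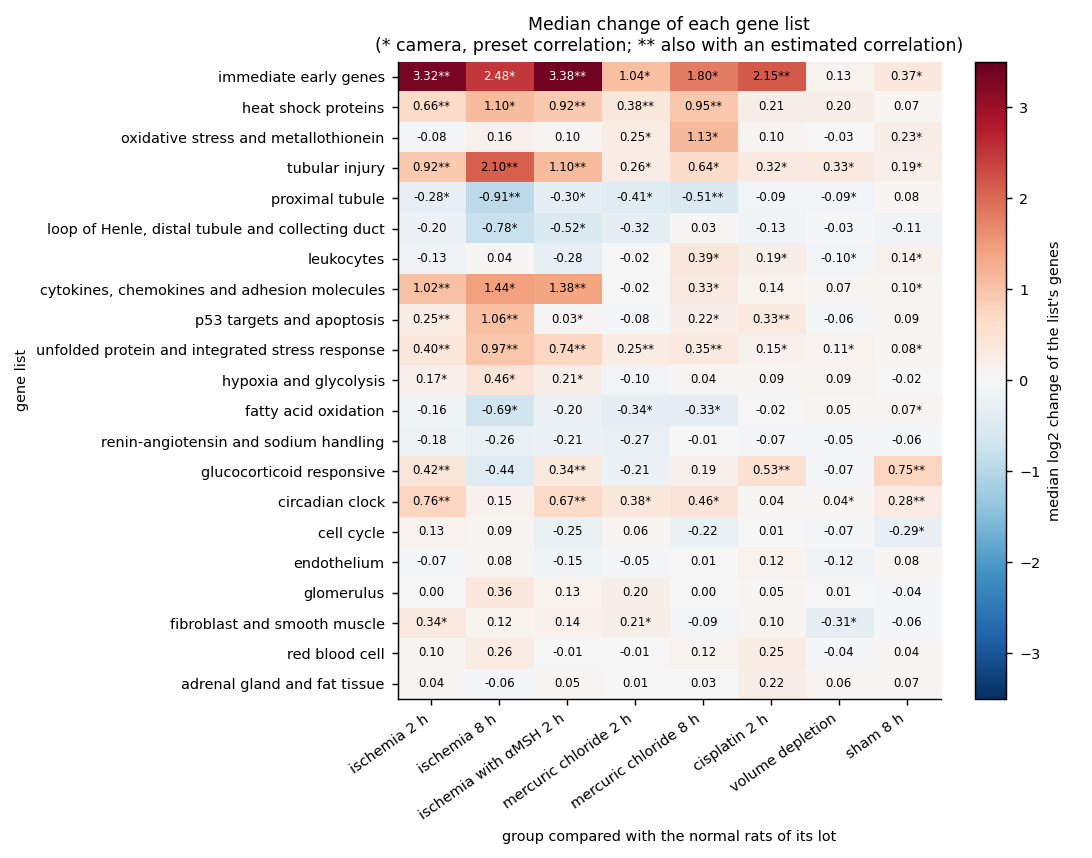
Median log2 change of each of the 21 gene lists in the 8 comparisons with normal rats, with 1 star for a camera call at the preset correlation and 2 stars where it also held with an estimated correlation. Immediate early genes had the highest median in ischemia with αMSH (3.38), and the proximal tubule list had the lowest in ischemia at 8 h (-0.91).

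Markers of other tissues were read beside these groups. None of the 8 adrenal gland and fat tissue genes passed in any comparison, and the median of the list against normal ran from -0.06 in ischemia at 8 h to 0.22 in cisplatin rats. Of 4 red blood cell genes, too few for a set test, 1 rose at 2 h of ischemia, the heme synthesis enzyme Alas2 (2.49 ± 0.44), and 2 rose and 1 fell at 8 h of ischemia. Of 10 fibroblast and smooth muscle genes 1 rose at 2 h of ischemia, the smooth muscle gene Tagln (1.10 ± 0.16; 2 rose adjusted over the list alone). The endothelium list had 4 genes up and 3 down of 11 at 8 h of ischemia, including the clotting factor gene Vwf (-1.81 ± 0.34), with a median of 0.08 and a mean of -0.06.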

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

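The test of the immediate early genes against random lists and that of the clock genes by arm were chosen only after the result was seen. The differences between groups in this part were tested by limma contrasts, with these counts of probes past the threshold: 1427 for ischemia against mercuric chloride at 2 h, 1121 at 8 h, 209 for ischemia against cisplatin and 90 for mercuric chloride against cisplatin at 2 h, 3580 for ischemia at 8 h against 2 h, and 69 for mercuric chloride at 8 h against 2 h. Of 52 sets of 4 or 5 values tested with Dixon's test, 3 had a value far from the others, where chance, at about 1 in 20, gives 2.6. Fndc1 in volume depletion rat 3 was at -1.41, against -2.68 to -2.48 in the other rats of the group. The median correlation of the first array of volume depletion rat 1 with its own group was 0.966, against 0.989 to 0.991 in the other rats, and that of its second array was 0.9899, so the low value belongs to 1 array and not to the rat. Normal rat 12 had 1.74% of probes missing, against 0.73% to 1% in the first arrays of the other normal rats, and 1.09% in the second array of normal rat 11.

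Other splits of the same rats were fitted to see whether arbitrary groups give as many probes. For 4 rats against 3 the share of splits as large as the real one was 1 of 35 in ischemia 2 h against normal (1395, highest other 609), volume depletion against normal (16, highest other 4), ischemia against mercuric chloride at 2 h (1427, highest other 445) and ischemia 8 h against 2 h (3580, highest other 2008). This share, the smallest that 35 splits allow, is under 0.05. It argues against chance for each comparison taken alone and does not exclude it, with no allowance made for the 16 comparisons. In volume depletion the count was also 7 without normal rat 1 and 1 when only the groups compared were fitted. For αMSH against ischemia the real count was 0 (342 at an unadjusted p under 0.05 in limma), which 35 of 35 splits reach by construction, so the splits say nothing about chance there. The highest other count was 71, from the split that puts ischemia rats 1 and 2 with αMSH rat 3. The 10 splits of the other comparisons with normal rats are too few for a share under 0.05. Real and highest other counts were 3946 and 2399 (ischemia 8 h), 1251 and 7 (αMSH), 727 and 1 (mercuric chloride 2 h), 1032 and 446 (mercuric chloride 8 h) and 33 and 3 (sham), each with 1 split as large, the real one. For cisplatin 2 of 10 were as large, with 55 real and 179 in the split that sets cisplatin rat 1 with the normal rats apart from cisplatin rats 2 and 3. That count, over 3 times the real one, points to a structure among the cisplatin rats.

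Across the lots 100 splits were drawn for each comparison. The splits as large were 3 of 100 for ischemia against cisplatin (209, highest other 324), and more for ischemia against mercuric chloride at 8 h (14 of 100; 1121, highest other 3073), mercuric chloride against cisplatin (7 of 100; 90, highest other 342), ischemia against sham (9 of 100; 2172, highest other 2461) and mercuric chloride 8 h against 2 h (10 of 100; 69, highest other 704). Of the other splits as large, 2 of 2, 13 of 13, 6 of 6, 8 of 8 and 8 of 9 in that order kept 1 real group apart from its normal rats, so their counts carry that group's own change from normal. These splits mix each group with its own normal rats and so test for no effect in either group, not for no difference between the groups, and the question of chance is left undecided for all 5.

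Glucocorticoid responsive genes were higher in sham (median 0.75) and cisplatin rats (0.52) than in the 2 normal rats of their lot, where low values of those shared normal rats are a candidate cause. Against the normal rats of lot 1, those normal rats had a list median of -0.36, with 8 of 10 genes lower. Set against the 3 mercuric chloride 8 h rats of the same lot, which does not use the normal rats, the list median in sham rats was 0.5. Of the 10 genes 7 were higher (camera p = 0.0243 with an estimated correlation). A fall of these genes in the mercuric chloride rats would give the same difference, so this test cannot decide on the shared normal rats. In cisplatin rats the median over the same group was 0.2, with 8 of 10 genes higher and a camera p of 0.121, a p that misses the threshold beside a median on the same side as over the normal rats, so low shared normal rats and a change in the cisplatin rats cannot be told apart. An adrenal response to surgery or injection is a biological explanation that was not tested, since no hormone level is used here.

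Immediate early genes were lower in the 2 normal rats of lot 2 than in the 3 of lot 1. Among 10000 random lists matched on mean expression the list median of -0.59 was at percentile 0, where 95% of lists lay between -0.23 and 0.13, which argues against lot effects that strike probes without regard to the gene. The mean of the list per rat was -0.16, -0.01 and -0.02 in lot 1 and -0.73 and -0.83 in lot 2, a gap of 6.9 SDs of lot 1. A difference in how rats of the lots were handled at tissue collection may account for this, but lot and series of rats coincide, and a state shared by a whole series leaves the same gap as a lot effect, so the bound written for that test decides nothing and the explanation stays open.

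In volume depletion rats Dbp was higher (2.11) and Bmal1 lower (-2.33) than in the normal rats of lot 1, from which the untreated normal rats of lot 2 differed in the same direction, with means of 3.83 against 2.18 for Dbp and 0.38 against 1.54 for Bmal1 and no overlap between their rats, where volume depletion rats had means of 4.29 and -0.79. Other lot 1 groups shifted too against the same normal rats. In the mercuric chloride 2 h rats Dbp stood at 1.14 to 1.49 and Bmal1 at -0.73 to -0.37. In the ischemia 8 h rats Bmal1 stood at -1.45 to -1.16, while Dbp ran from -0.20 to 0.44. The shift was thus not particular to volume depletion, and part of it may lie in the lot 1 normal rats. The tables argue against a single rat or array as the cause, since 90.1% or more of both changes was left when each rat or the doubted arrays were left out, and all 10 such fits stayed past the threshold. A different time of day at tissue collection may be a cause: of 8 clock genes with a known arm, all 5 past the threshold over the list went with their arm, and 7 of 8 in all, with Per1 (-0.29) against it. The 5 include Dbp and Bmal1, which prompted the test, so only Tef (1.07), Nr1d2 (0.89) and Bhlhe41 (0.88) add to it, and this stays a hypothesis. These rats were given furosemide and a low-sodium diet, and an effect of the drug, the diet or fluid loss on the clock was not tested and stays open. The normal rats of lot 2 do not bear on it, since they also differ from those of lot 1 in array lot. The treated rats of lot 2 had Dbp at 3.375 to 4.582 and Bmal1 at -0.613 to 0.854. A lot effect on these probes and a difference between the normal rats cannot be told apart.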

How the results depend on the processing

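The tests chosen only after the data were seen were those with the deposited order of sham rat 3, array weights, no doubted arrays, normal rats left out across lots, no lot term for the lists, and rats left out for the shared probes. Of the values of named genes recomputed under the alternatives, 16169 kept their side of the threshold, 944 were no longer past it, 107 newly passed it and 4 turned. A turn was counted only where the value was past the threshold in the main fit or in the alternative. The 16169 can therefore include values past it in neither fit whose sign changed. The 4 that turned were Dbp in ischemia with αMSH (-0.03), Per1 in mercuric chloride 8 h (-0.02) and Dbp in mercuric chloride 2 h against cisplatin (0.00), all with no lot term, and Lrrc28 in mercuric chloride 8 h without normal rat 12 (0.01, against -3.52 without normal rat 11 and -1.75 with both). No floor, a floor of 0.3, no filter on dim probes, a trended and robust prior and the first array of each rat moved no count of probes by more than 1.5 times. Counts are of probes, and unless another group is named a comparison is with normal rats. A similar count need not mean the same probes. Mercuric chloride 8 h had 1197 with only the groups compared, 811 of them called in the same direction in the main fit. Cisplatin had 5 in that setting, 2 of them called in the same direction in the main fit. Where no reason is given below, the cause was not tested.

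With sham rat 3 in the deposited order the counts fell to 300 (ischemia 2 h), 1306 (8 h), 243 (with αMSH), 63 (mercuric chloride 2 h), 153 (8 h), 4 (cisplatin), 2 (volume depletion) and 0 (sham). They were 261 and 112 for ischemia against mercuric chloride at 2 h and 8 h, 34 for ischemia against cisplatin, 6 for mercuric chloride against cisplatin, 503 for ischemia against sham, 956 for ischemia 8 h against 2 h and 4 for mercuric chloride 8 h against 2 h. Probes shared by both injuries numbered 28 up and 3 down at 2 h, and 68 and 56 at 8 h. By construction this setting gives 1 array wrong values for nearly all probes, which widens the spread that all groups share. In the deposited order and with no lot term the counts were 468, 1656, 361, 94, 430, 19, 3 and 3814 in the first order, then 241 (ischemia 2 h against mercuric chloride), 498 and 255 (against cisplatin), 3428 (against sham), 935 and 154 (8 h against 2 h).

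Array weights gave 2966 (ischemia 2 h), 2803 (αMSH), 2868 and 2964 (mercuric chloride 2 h and 8 h), 319 (cisplatin), 524 (volume depletion) and 532 (sham). They also gave 2905 and 3048 for ischemia against mercuric chloride, 917 for ischemia against cisplatin, 1010 for mercuric chloride against cisplatin, 4367 for ischemia against sham and 1125 for mercuric chloride 8 h against 2 h. The weights ran from 0.03, for ischemia 8 h rat 3, to 4.22. Without the doubted arrays (ischemia 8 h rat 3, normal rat 1 and the first array of volume depletion rat 1) the counts were 1993 (mercuric chloride 8 h), 112 (cisplatin), 48 (volume depletion), 61 (sham), 2539 and 1694 (ischemia against mercuric chloride), 365 and 258 (against cisplatin) and 217 (mercuric chloride 8 h against 2 h). Volume depletion then had 2 lists called, and the shared probes were 243 up at 2 h, 579 up at 8 h and 870 down at 8 h.

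No lot term gave 2145 (mercuric chloride 8 h), 509 (cisplatin), 41 (volume depletion), 249 (sham), 3122 (ischemia against mercuric chloride 8 h), 2418 and 2215 (against cisplatin), 4191 (ischemia against sham) and 1633 (mercuric chloride 8 h against 2 h). The lists called were then 3 (cisplatin), 2 (sham), 5 (ischemia against mercuric chloride 8 h), 5 and 3 (against cisplatin) and 1 (mercuric chloride 8 h against 2 h), and the shared probes 217 up and 186 down at 2 h and 818 down at 8 h. In this setting groups of lot 2 are set against normal rats of both lots.

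By construction fewer probes pass stricter thresholds. A fold of at least 2 left 312 (ischemia 2 h), 1234 (8 h), 323 (αMSH), 132 and 288 (mercuric chloride), 9 (volume depletion), 287 and 533 (ischemia against mercuric chloride), 138 (ischemia against cisplatin), 1064 (ischemia against sham) and 777 (ischemia 8 h against 2 h). An adjusted p under 0.01 left 850 (ischemia 2 h), 661 (αMSH), 327 and 586 (mercuric chloride), 21 (cisplatin), 7 (volume depletion) and 12 (sham), then 831 and 536 (ischemia against mercuric chloride), 94 and 33 (against cisplatin), 1314 (ischemia against sham) and 29 (mercuric chloride 8 h against 2 h). Probes above the median brightness, fewer to test, gave 796, 2597 and 680 for the ischemia groups at 2 h, 8 h and with αMSH, 792 against mercuric chloride 2 h, 112 against cisplatin and 2356 for 8 h against 2 h. Fitting only the groups compared, which leaves fewer rats for the spread, gave 1487 (ischemia 8 h), 715 (αMSH), 411 (mercuric chloride 2 h), 5 (cisplatin), 1 (volume depletion), 91 (sham), 1 (αMSH against ischemia), 236 (ischemia against mercuric chloride 8 h), 1128 (ischemia against sham) and 1632 (ischemia 8 h against 2 h). Quantile normalization gave 163 (mercuric chloride against cisplatin) and 158 (mercuric chloride 8 h against 2 h), and the rat as a random block gave 50 (sham).

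An estimated correlation left 4 lists called in ischemia 8 h, 7 with αMSH, 2 and 3 in mercuric chloride 2 h and 8 h, 3 in cisplatin, 0 in volume depletion and 2 in sham, with 0 for αMSH against ischemia, 0 and 0 for ischemia against mercuric chloride, 3 and 1 against cisplatin, 2 against sham, and 0 and 0 for 8 h against 2 h. By construction it allows for the correlation between genes of a list.

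Leaving out each rat in turn gave ranges of 1010 to 1310 (ischemia 2 h), 3381 to 4346 (8 h), 784 to 1280 (αMSH), 370 to 668 and 472 to 1079 (mercuric chloride 2 h and 8 h), 15 to 142 (cisplatin), 7 to 20 (volume depletion) and 9 to 30 (sham). Between treated groups they were 0 to 2 (αMSH against ischemia), 999 to 1255 and 605 to 1611 (ischemia against mercuric chloride), 102 to 305 and 33 to 154 (against cisplatin), 1476 to 2903 (ischemia against sham), 3095 to 3833 and 30 to 98 (8 h against 2 h). The shared probes ran from 93 to 142 up and 28 to 123 down at 2 h, and from 191 to 383 up and 193 to 457 down at 8 h. Counts moved by more than 1.5 times without the rats named here. They were 791 without normal rat 1 and 784 without αMSH rat 1 for αMSH, and 474, 480, 418 and 370 without normal rats 1 and 2 and mercuric chloride rats 3 and 1 for mercuric chloride 2 h. For mercuric chloride 8 h they were 505 and 472 without normal rats 11 and 12. Cisplatin had 15, 29 and 142 without cisplatin rats 2, 3 and 1 and 18 without normal rat 12, volume depletion had 7 and 10 without normal rats 1 and 3 and 8 without its rat 3, and sham had 9, 17 and 13 without sham rats 1, 2 and 3 and 11 without normal rat 12. αMSH against ischemia had 2 without αMSH rat 3 and 1 without ischemia rat 3. Without normal rats 11 and 12 the counts were 734 and 605 for ischemia against mercuric chloride 8 h and 121 and 102 for ischemia against cisplatin, and without normal rat 12 it was 30 for mercuric chloride 8 h against 2 h. Mercuric chloride against cisplatin had 33 without normal rat 12, 53 without mercuric chloride rat 3, and 57 and 154 without cisplatin rats 2 and 1. The shared probes down at 2 h were 28 without normal rat 1 and 63 and 60 without mercuric chloride rats 3 and 1, and at 8 h there were 214 and 191 up and 193 and 199 down without normal rats 11 and 12. With 1 normal rat left in lot 2, that rat was assumed to vary like the rats of the other groups.

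The numbers up and down changed more than the totals in several comparisons. Without ischemia 8 h rat 3 the larger part turned from higher to lower for ischemia 8 h against 2 h (1651 and 1969), against mercuric chloride 8 h (721 and 890) and against sham (1249 and 1654), and without the doubted arrays in the first and last of these (1830 and 2140, 1402 and 1579). It also turned without the doubted arrays for mercuric chloride 8 h against 2 h (103 and 114), mercuric chloride 2 h against cisplatin (140 and 118) and mercuric chloride 2 h against normal (528 and 519). With array weights it turned for ischemia 8 h against 2 h (2215 and 2479) and against sham (2068 and 2299), for mercuric chloride 8 h against 2 h (532 and 593), αMSH (1239 and 1564), volume depletion (303 and 221) and sham (265 and 267). In ischemia 8 h the numbers up and down ran from 1835 and 2511 without its rat 3 to 2192 and 1766 without its rat 1. Mercuric chloride 2 h had 77 up and 55 down at a fold of at least 2. Without normal rat 1 the falls were 352 of 1010 in ischemia 2 h, 235 of 791 with αMSH and 194 of 474 in mercuric chloride 2 h. Quantile normalization turned it for αMSH (680 and 792), ischemia against mercuric chloride 2 h (753 and 896) and mercuric chloride against cisplatin (88 and 75), and no lot term for αMSH (768 and 849) and ischemia against cisplatin (1047 and 1371). Probes above the median brightness turned it for ischemia 8 h against 2 h (1125 and 1231), against mercuric chloride 8 h (370 and 381) and against sham (676 and 823). An excess of rises or falls in these comparisons therefore depends on the setting.

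Replicate numbers did not pair the rats. The median correlation of residuals was 0.019 over 109 pairs of rats with the same number and -0.005 over 316 pairs with different numbers, and a replicate block with the lot term gave 1339 (ischemia 2 h), 3907 (8 h), 1188 (αMSH), 696 and 1024 (mercuric chloride), 55 (cisplatin), 14 (volume depletion), 33 (sham) and 0 (αMSH against ischemia). That block also gave 1395 and 1098 (ischemia against mercuric chloride), 207 and 82 (against cisplatin), 2144 (ischemia against sham), 3522 and 67 (8 h against 2 h).

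The limits are the 2 normal rats of lot 2, on whom the changes from normal in sham, cisplatin and 8 h mercuric chloride rats rest, the lots read from the values, and the signal over background, with 1.65% to 12.91% of probes of an array at the floor. Another limit is that no sham rats were studied at 2 h. The 2 h ischemia groups, with and without αMSH, therefore carry surgery in every comparison with rats that had none. On simulated data 33.1% of 1.5-fold and 74.3% of 2-fold changes were recovered for mercuric chloride 8 h against normal, against 50.4% and 83.6% for ischemia 2 h.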
